A study of Homo sapiens with 3 samples.

How the data were processed

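Total RNA of MDA-MB-231 cells was profiled on 3 Illumina bead arrays labelled with Cy3, 1 each for cells transfected with an FBP1 expression vector, cells of a control named wt and cells transfected with an empty vector. Per the labels' protocols, cells grew in DMEM with 10% serum at 37 °C and 5% CO2, RNA was adjusted to 100 ng/µl, and labelling followed the array maker's protocol. The groups were taken from the labels. Whether the cultures were handled in parallel was not given in the sources used here.

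The first deposited table holds a signal intensity per probe and array on a linear scale; per the file headers it also holds a detection p-value beside each intensity. The scanner software, and how the authors summarised beads, were not given in the sources used here. The lowest intensities were 66.9, 63.3 and 68.2 on the FBP1, wt and empty vector arrays, so background had not been subtracted, and the medians differed between arrays, so the values had not been normalised between arrays. The second deposited table holds the authors' processed intensity of the same probes, on a linear scale and not centred per gene. Its medians of 87.8, 87.8 and 87.9 show a normalisation between arrays whose method was not given in the sources used here. Each of its columns ranked the probes as the same sample's first table did (Spearman correlation across probes of at least 0.9997), and as other samples' less closely (at most 0.839). The table of 48107 probes lacked 2 signals on the empty vector array, and probes with a missing value were left out.

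Intensities were background-corrected and quantile normalised with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16, and taken as log2. Background was estimated from the detection p-values, since no control probes are marked in the table. The estimated background means were 85.7, 87.2 and 88.0 on the FBP1, wt and empty vector arrays and the standard deviations 4.2, 16.2 and 12.8. The deposited detection p-values are not a function of the intensity alone, as the method assumes, so the background spread is uncertain; normexp fitted to all probes with an offset of 50 was added as an alternative after this was seen. Probes were matched to genes through the platform's annotation: 30113 probes had 1 gene, 8 had several and were not used, and 17986 were unnamed here. Of the probes with 1 gene, 30074 matched the RefSeq gene table of assembly GRCh38 by gene ID and took their current symbol from it. No coordinates are given because the files name no genome build. Each gene was read from its brightest probe, which gave 20046 genes, and a gene entered a comparison if its detection p-value was under 0.01 on at least 1 of the arrays compared. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

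Differences were taken between the FBP1 and empty vector arrays (the main comparison), the FBP1 and wt arrays, and the empty vector and wt arrays. The series design names the empty vector as the control of the FBP1 vector, and the labels call the wt array a control too. With 1 array per group there is no test across samples, so genes were counted by size, at least 1.5-fold and at least 2-fold, and a gene apart from both controls had to reach that size against each. The number of arrays limits the precision of every value. Where a gene was not detected on the dimmer array, its fold is given as a lower bound, against the higher of the gene's own level there and the lowest level of any detected probe on that array (4.68, 4.69 and 4.70 on the FBP1, wt and empty vector arrays); that limit is "near the detection limit" in the text. The chance effect of a shared array was simulated 100 times with noise drawn from the difference between the controls.

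The 35 gene lists covered carbon metabolism, signalling pathways, cell state, cell cycle, stress responses, lipid synthesis, loading and RNA handling, and markers of other cell types; the report gives the result of each. For each list the median difference of its detected members was placed among 10000 random lists of the same size matched on mean level in 20 bins, and a list lay outside them below percentile 2.5 or above percentile 97.5. The genes named were fixed by rule: FBP1; the 12 highest and 12 lowest by the smaller of both differences from the controls, detected on the FBP1 array or on both controls; the 5 highest and 5 lowest between the controls; and the 2 highest and 2 lowest members of each list against the empty vector array. Unnamed probes and provisional gene names were passed over. The lists, the rule, the comparisons and all alternatives except those named as added were chosen before the data were examined. Y-linked genes and XIST count in the totals and are not reported by name. A check of the arrays against one another on such genes, chosen after the data were seen, left 1 of the 3 arrays out of place with its label.

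The steps were tested on simulated arrays with known folds. Their noise was normal and scaled to the central spread of the difference between the controls, so rarer large differences were left out. The shares that follow may therefore be too favourable, and the share of unchanged genes called too low. Genes given a fold were drawn only from those detected on all 3 arrays, so their shares do not cover genes detected on fewer. With a real control array in the FBP1 array's place, 3.3% (wt) and 1.7% (empty vector) of 12895 genes stood apart from the other arrays. Of the genes set 2-fold higher on the array in the FBP1 position, 85.3% were called at least 1.5-fold above both controls, and of those set 2-fold lower 60.6% were called below both; at 4-fold the share was 100.0% in each direction, at 1.5-fold it was 32.4% and 33.3%, and 1.26% of unchanged genes were called, among 12808 genes in that step. Alternatives tried were no background correction, an offset of 50, scaling to a common median, cyclic loess, a detection p-value under 0.05, no detection filter, the mean over a gene's detected probes, the authors' processed values and the mean of both controls in place of the empty vector.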

Results

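Gene expression was measured on Illumina bead arrays in MDA-MB-231 cells, an established human breast cancer line of the triple-negative, mesenchymal-like type. The series set cells given extra FBP1 (fructose-1,6-bisphosphatase 1), the gluconeogenic enzyme that works against the phosphofructokinase step of glycolysis, beside control cells. There were 3 arrays in 3 groups of 1: cells transfected with an FBP1 expression vector, cells transfected with the empty vector, and a control named wt, whose handling the labels do not describe. At a detection p-value under 0.01, 20190 probes were detected on the FBP1 array, 20117 on the wt array and 20168 on the empty vector array, between 41.8% and 42.0% of the probes on each. The median signals were 91.7, 93.7 and 94.6 intensity units, and the median signals of the authors' processed table were 87.8, 87.8 and 87.9. With 1 array per group no difference had a replicate check, no p-value could be given for a comparison, and every difference is between single arrays. The check described above left 1 of the 3 arrays out of place with its label, which limits every comparison below. Levels are normalised log2 intensities and differences are log2 unless a fold is named.

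FBP1 itself was highest on the FBP1 array. Its 1 probe (ILMN_1728799) gave signals of 1063.5 on the FBP1 array, 678.6 on the empty vector array and 530.8 on the wt array, which became log2 levels of 10.06, 9.22 and 8.77. The FBP1 array was 1.79-fold above the empty vector array and 2.44-fold above the wt array, and the empty vector array was 1.37-fold above the wt array. FBP1 was clearly detected on both controls. Of 12895 detected genes, 317 lay further above the empty vector array than FBP1 did and 112 lay further above the wt array. Where the probe lies relative to the vector's insert was not given in the sources used here, so the probe may miss transcripts of the vector and cannot settle how strongly FBP1 was expressed from it.

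The comparison with the empty vector was the main one, and the genes named first were those that also stood apart from the wt control. UCHL1, a neuronal ubiquitin hydrolase, had a level of 9.14 on the FBP1 array and was detected on neither control, which made it at least 21.7-fold higher than on the empty vector array and at least 21.8-fold higher than on the wt array. The chemokine gene CCL20 was 13.3-fold above the empty vector array and 8.33-fold above the wt array. PHGDH, which catalyses the first step of serine synthesis from glycolytic 3-phosphoglycerate, was at least 10.4-fold above the empty vector array and 7.80-fold above the wt array. CSF1, the macrophage growth factor gene, was 5.47-fold and 5.76-fold higher, and LTB, which encodes lymphotoxin beta, was 4.33-fold and 9.43-fold higher. CDH1, which encodes the epithelial adhesion protein E-cadherin, was detected on the FBP1 array alone, at a level of 6.54, and was at least 3.5-fold above each control.

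The other genes farthest above both controls were TMEM98 (at least 4.8-fold above the empty vector array), BCHE (at least 5.2-fold), FAM83A (4.50-fold), the secreted hormone gene STC2 (at least 4.7-fold), DPYSL3 (at least 3.8-fold) and the complement gene CFB (3.79-fold). Against the wt array, TMEM98 was at least 5.1-fold higher, BCHE 4.75-fold, FAM83A 5.51-fold, STC2 3.87-fold, DPYSL3 at least 3.8-fold and CFB 4.56-fold.

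The genes farthest below both controls included CENPE, the kinetochore motor of mitosis, which was 3.84-fold below the empty vector array and 4.14-fold below the wt array. SGO2, which protects cohesion at the centromere, differed by -1.32 and -1.36 (log2). The protease inhibitor gene SERPINA3 was 4.89-fold and 5.30-fold lower, and MAOA, which encodes monoamine oxidase A, was 2.68-fold and 4.44-fold lower. For a number of genes the controls themselves were far apart. The monocyte chemokine gene CCL2 was 3.63-fold below the empty vector array and 20.8-fold below the wt array, HSPA6 was 4.75-fold and 19.4-fold lower, IL7R 3.22-fold and 10.05-fold lower, and PSG4 5.25-fold and 11.3-fold lower. RPL36A (2.72-fold and 4.15-fold), SCARA3 (2.73-fold and 2.57-fold), NLE1 (2.54-fold and 2.71-fold) and CYB5R2 (2.44-fold and 3.27-fold) completed the 12 lowest genes. HSPA6, PSG4 and RPL36A have close copies elsewhere in the genome, so their probes may read more than the gene named.

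**Figure D1:**
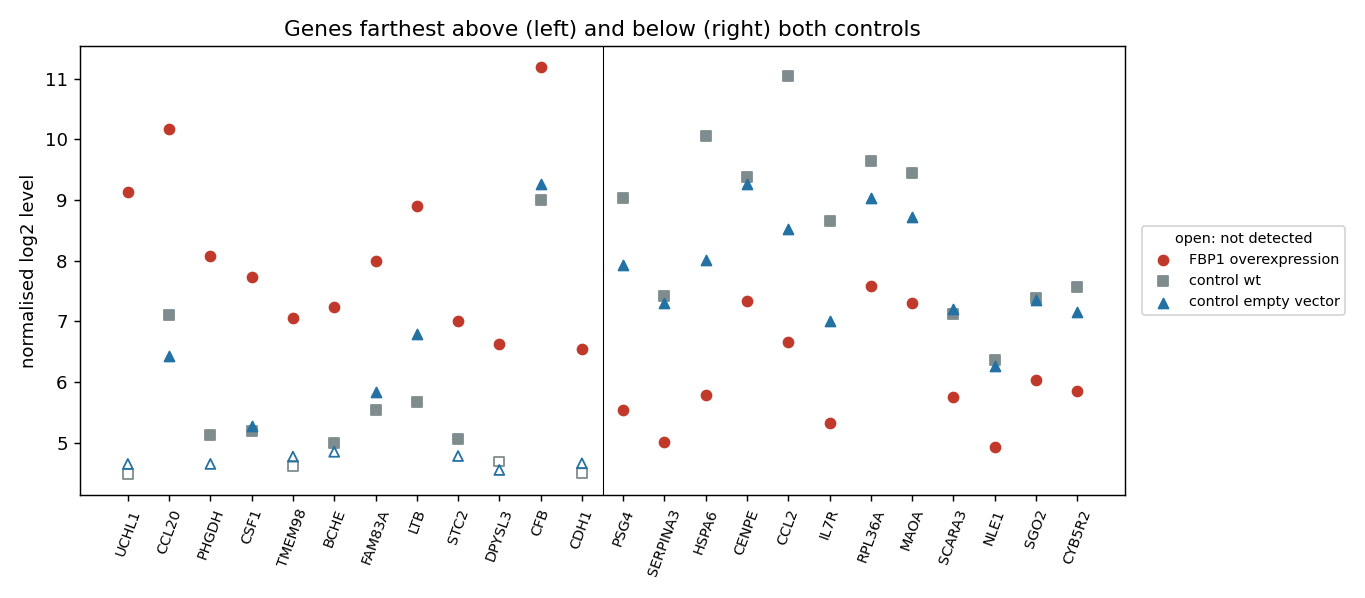
Normalised log2 level (vertical axis) on each of the 3 arrays of the 12 genes farthest above both controls (left of the line) and the 12 farthest below both (right), with 1 array per group and open symbols where the gene was not detected. UCHL1 stood at 9.14 on the FBP1 array and near the detection limit on both controls, and CENPE at 7.33 against 9.27 and 9.38.

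Of 12413 genes detected on at least 1 of the FBP1 and empty vector arrays, 839 were at least 1.5-fold higher on the FBP1 array and 751 at least 1.5-fold lower, so that 52.8% of these differences were upward; with the authors' processed values, which are not background-corrected, 65.0% were upward, and with median scaling 46.1% (845 higher and 987 lower), so neither direction prevailed under all settings. Against the wt array the counts were 1111 higher and 992 lower of 12404 genes. The FBP1 array was at least 1.5-fold above both controls for 519 genes and below both for 394, of 12895 detected genes, and 56.8% of these were upward (69.1% with the authors' processed values and 50.8% with median scaling). At 2-fold the counts were 84 and 51. When a control array took the FBP1 array's place, the wt array stood apart from the other arrays for 228 genes upward and 200 downward, and the empty vector array for 142 and 77.

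Both differences share the FBP1 array and so go together by chance. Simulated unchanged arrays, with noise drawn from the difference between the controls, gave 133.2 genes above both and 136.8 below both, and independent lists of the observed sizes would share 72.8 and 57.9 genes. The correlation of both differences across genes was 0.717 against 0.502 in the simulation, and the covariance was 0.134 against 0.055. With a control in its place the covariance was 0.0821 for the wt array and 0.0275 for the empty vector array. Both values add up to the variance of the difference between the controls, which the simulation split equally between arrays. A value above 0.055 for either control therefore puts the other below it, so setting the controls against the simulation decides nothing. Genes are not independent replicates, and part of the excess may come from the shared array.

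**Figure D2:**
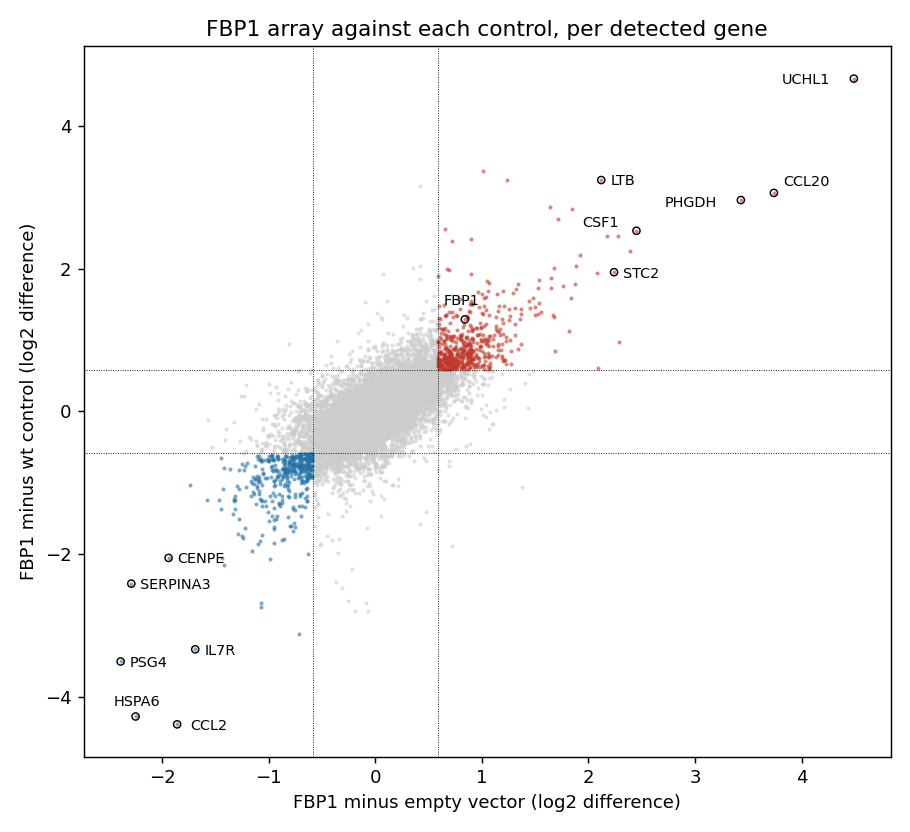
Log2 difference of the FBP1 array from the empty vector array (horizontal axis) and from the wt array (vertical axis), 1 point per detected gene, with genes at least 1.5-fold above both controls in red, those at least 1.5-fold below both in blue, and dotted lines at 1.5-fold. UCHL1, which was detected on neither control, lies at 4.49 and 4.66, and FBP1 at 0.84 and 1.29.

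Genes of cell division were lower on the FBP1 array. Of 28 detected genes of the G2 and M phases, 19 were at least 1.5-fold below the empty vector array and 20 below the wt array, and none was higher by that much than either. The list median was -0.77 against the empty vector array and -0.70 against the wt array, below all 10000 random lists matched on level in both comparisons, and it was 0.05 between the controls. The mitotic kinesin gene KIF20A stood at -1.32 and CENPE at -1.94 against the empty vector array, while the members nearest to 0 were HMMR at -0.38 and PTTG1 at -0.39. Of 25 detected S phase genes, 7 were at least 1.5-fold below the empty vector array and 7 below the wt array, with 4 below both, and none was that much higher, with medians of -0.40 and -0.47. GINS2, part of the replicative helicase, stood at -0.96 against the empty vector array and the replication licensing gene CDC6 at -0.93, while CLSPN (0.03) and FEN1 (-0.11) were close to 0. Replication-dependent histone genes had medians of -0.57 and -0.79, with 5 of 10 members at least 1.5-fold below the empty vector array, among them H2AC20 (-1.33) and H2AC18 (-1.04), whereas H2BC5 (-0.10) and H4C3 (-0.42) did not reach that size. Histone genes are near-identical copies of one another, so their probes cannot be assigned to single genes with certainty.

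MYC targets, mostly genes of ribosome assembly, had medians of -0.26 against the empty vector array and -0.60 against the wt array, but the empty vector array was itself below the wt array by a median of -0.32. Of 21 detected members, 3 were at least 1.5-fold below the empty vector array, including the polyamine synthesis genes ODC1 (-0.83) and SRM (-0.77), and none was above; RRP12 stood at 0.25 and POLR1B at 0.13. Heat shock genes had medians of -0.17, outside the random lists in only 4 of 9 alternative settings, and -0.21, with 2 of 14 members at least 1.5-fold below the empty vector array, HSPA6 (-2.25) and the collagen chaperone gene SERPINH1 (-0.87), while HSPH1 stood at 0.39 and HSPA1B at -0.02.

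Hypoxia-related genes were higher on the FBP1 array. Of 22 detected targets of the HIF transcription factors, 9 were at least 1.5-fold above the empty vector array and 10 above the wt array, none was that much lower, and the medians were 0.50 and 0.53, above all 10000 random lists, against 0.06 between the controls. STC2 (at least 4.7-fold higher) and the collagen-crosslinking enzyme gene LOX (1.06) stood highest against the empty vector array, and JMJD6 (-0.47) and BNIP3L (-0.03) lowest. Of 18 detected cholesterol synthesis genes, 8 were at least 1.5-fold above the empty vector array and none below, with medians of 0.47 and 0.34; LSS, which closes the sterol ring, stood at 1.23 and HSD17B7 at 1.00, and SREBF2 (-0.33) and PMVK (-0.18) stood lowest.

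The list of inflammatory genes driven by NF-kB had a higher median than on both controls, but its members went both ways, with 7 of 25 at least 1.5-fold above both controls and 1 below both. Of the 25 detected members, 13 were at least 1.5-fold above the empty vector array and 1 below, and 8 were above the wt array and 4 below. The medians were 0.78 (0.30 with no detection filter and 0.39 with the authors' processed values) and 0.35, and the empty vector array lay below the wt array by a median of -0.56. CCL20 (3.74) and the cyclooxygenase gene PTGS2 (2.29) stood highest against the empty vector array, while CCL2 (-1.86) and MMP3 (-0.45) went the other way. Interferon-stimulated genes had medians of 0.31 and 0.23, with 13 of 35 members at least 1.5-fold above the empty vector array and 1 below. Against the wt array 8 were above and 2 below, and 6 of the 35 were above both controls. CXCL10 (1.18) and DDX60 (1.08) stood highest against the empty vector array and SAMD9L (-0.94) and OAS3 (-0.55) lowest.

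Markers of luminal breast cells, a cell type other than the one cultured, had medians of 0.44 and 0.34 over 11 detected markers of 15. Of the 11, 4 were at least 1.5-fold above the empty vector array and none below. The markers ESR1, PGR, GATA3 and TFF1 were not among those detected. With no detection filter the median against the empty vector array was 0.07, inside the random lists. FOXA1 was detected on the FBP1 array alone, at least 3.3-fold above each control, and AGR2 stood at 1.34, while KRT8 stood at -0.51 and TFF3, not detected on the FBP1 array, was at least 1.2-fold lower. The empty vector array lay above the wt array on this list too, by a median of 0.20. That difference lay above the random lists in the main setting and in 9 of 9 alternative settings. Markers of fibroblasts had medians of 0.13 and 0.41 (PDGFRB 0.60, DPT at least 1.4-fold higher, ACTA2 0.00 and THY1 at least 1.2-fold lower against the empty vector array). The difference from the wt array lay outside the random lists here, but in only 1 of 9 alternative settings. Markers of blood cells had medians of -0.13 and -0.06, inside the random lists (CD14 1.04, HBA2 at least 1.5-fold higher, LCP1 -0.41 and CORO1A at least 1.3-fold lower against the empty vector array).

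Glycolytic genes, the pathway FBP1 opposes, stood slightly above the empty vector array, with a median of 0.13 at percentile 98.17 of the random lists, and 0.15 against the wt array at percentile 95.89, inside the random lists (outside them in 2 of 9 alternative settings). Of 23 detected members, 3 were at least 1.5-fold above the empty vector array and none below. PFKFB4, which makes the activator of phosphofructokinase, was 1.85-fold higher and ALDOC 1.79-fold higher, while SLC16A7 (-0.29) and PFKFB2 (at least 1.1-fold lower) stood lowest. Gluconeogenesis and glycogen genes had medians of -0.05 and 0.08, with PC at 0.57 and PGM2 at -0.51 against the empty vector array. The pentose phosphate pathway had medians of -0.05 and -0.06, oxidative phosphorylation -0.05 and -0.01 with none of 43 members 1.5-fold away from the empty vector array, and the pyruvate dehydrogenase and TCA cycle genes -0.14 and -0.17, all inside the random lists; the last of these lay outside them against the wt array in 7 of 9 alternative settings and against the empty vector array in 1. In that list, PDK4, an inhibitor of pyruvate dehydrogenase, stood at 0.72 and the mitochondrial isocitrate dehydrogenase gene IDH2 at -1.04. The serine, glycine and one-carbon genes did not move together with PHGDH, with medians of 0.19 and -0.01 over 10 members and with MTHFD1 (-0.55) and TYMS (-0.57) lowest.

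Epithelial genes did not stand apart from the empty vector array as a group (median 0.07). They lay above the random lists against the wt array (0.38), but in only 4 of 9 alternative settings. Of 13 detected members, 5 were at least 1.5-fold above the empty vector array, led by CDH1 and by the mucin gene MUC1 (1.71), and KRT8 (-0.51) and CRB3 (-0.46) stood lowest. Mesenchymal genes had a median of -0.28 against the empty vector array, below the random lists, and -0.04 against the wt array, inside them; CDH11, a mesenchymal cadherin, stood at -0.93 and MMP14 at -0.79, and S100A4 at 0.42. Wnt targets had a median of -0.26 against the empty vector array, below the random lists, and -0.14 against the wt array, inside them. LEF1, a transcription factor and target of Wnt signalling, was 2.18-fold below the empty vector array and 1.92-fold below the wt array, and the Wnt inhibitor gene ZNRF3 was 2.08-fold and 1.43-fold lower, whereas BMP4 was 1.90-fold and 1.79-fold higher.

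Several lists stood above the random lists against the empty vector array and inside them against the wt array. These were the integrated stress response (medians 0.32 and 0.20, with CTH at 1.19 and SLC7A5 at -0.47 against the empty vector array), the unfolded protein response (0.23 and 0.11, with the chaperone gene HSPA5 at 0.90 and CALR at -0.45), fatty acid synthesis and storage (0.27 and 0.17, with LPIN1 at 1.04 and ELOVL6 at -0.47) and immediate early genes (0.20 and 0.13, with ATF3 at 1.00 and NR4A1 at least 1.5-fold lower). The targets of YAP and TEAD had medians of -0.12 and -0.20, extracellular matrix and invasion genes 0.04 and 0.33, and antigen presentation genes 0.03 and 0.35; in each the difference from the wt array alone lay outside the random lists, for YAP and TEAD targets in 7 of 9 alternative settings. Targets of p53 (0.00 and 0.15, with GDF15 at 1.67), NRF2 and oxidative stress genes (-0.10 and -0.07, with AKR1C3 at 0.96 and NQO1 at -0.68), Notch targets (-0.28 and 0.04, with HES4 at -1.08) and breast stem-like markers (-0.15 and -0.13, with CD24 at 0.90) lay inside the random lists in both comparisons, as did ribosomal protein genes (-0.04 and -0.05), housekeeping genes (-0.02 and -0.16) and short-lived transcripts (0.06 and 0.08). Of these, Notch targets lay outside the random lists against the empty vector array in 2 of 9 alternative settings, and stem-like markers against the wt array in 2 and ribosomal protein genes in 1. CD24 is in the stem-like list although such cells are marked by a low level of it, so its 0.90 does not point to them.

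Of 35 lists, 17 lay outside the random lists against the empty vector array, 15 against the wt array and 9 between the controls, where 1.75 would be outside by chance if genes were independent. There were 10 lists outside on the same side against both controls. Random lists draw genes one by one, whereas members of a pathway vary together, so lying outside them describes these arrays and is no test.

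**Figure D3:**
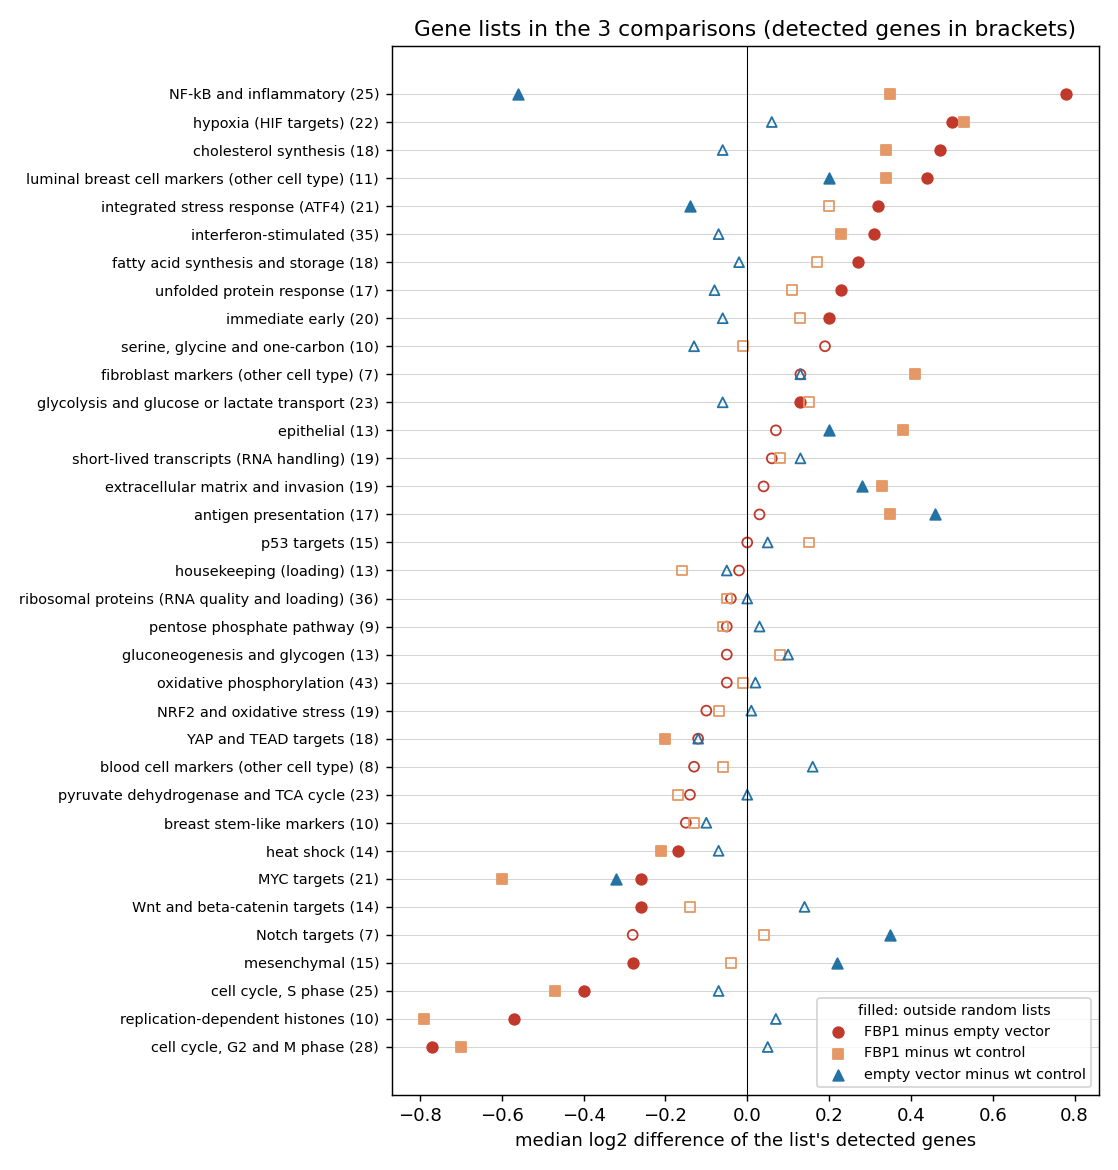
Median log2 difference (horizontal axis) of each of 35 gene lists in the 3 comparisons, with the number of detected genes in brackets and filled symbols where the median lay outside the random lists. The G2 and M phase list stands at -0.77 and -0.70 against the controls and at 0.05 between them, and the NF-kB list at 0.78, 0.35 and -0.56.

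The controls were compared with each other to see how far arrays without the FBP1 vector lay apart. The empty vector array was higher for cystatin genes, with CST2 6.65-fold, CST4 5.12-fold and CST1 3.99-fold above the wt array, and for the transporter gene SLCO4A1 (3.77-fold) and the transcription factor gene SOX4 (3.64-fold). SPANXA2 was 6.60-fold lower, SPANXB1 6.01-fold lower and SSX1 at least 6.0-fold lower. The decoy receptor gene IL13RA2 was at least 6.0-fold lower and CCL2 5.73-fold lower. The FBP1 array was close to the empty vector array for SPANXA2 (-0.07), SPANXB1 (-0.09) and SOX4 (0.07), and SSX1 was detected on neither. It was above the empty vector array for CST1 (1.24), CST4 (2.01-fold), IL13RA2 (at least 1.6-fold), SLCO4A1 (0.65) and CST2 (0.42), and below it for CCL2 (-1.86). CST and SPANX genes are families of near-identical copies, so the copy that was read is uncertain.

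Of 12344 genes detected on at least 1 of the control arrays, 493 were at least 1.5-fold higher on the empty vector array and 414 lower. Antigen presentation genes had a median of 0.46, extracellular matrix and invasion genes 0.28, mesenchymal genes 0.22, epithelial genes 0.20, luminal markers 0.20 and Notch targets 0.35, all above the random lists. Luminal markers stayed there in 9 of 9 alternative settings, epithelial genes in 6 and Notch targets in 3. The NF-kB list (-0.56), the MYC targets (-0.32) and the integrated stress response (-0.14) lay below them. The standard deviation of the difference across 12895 genes was 0.33 between the controls, 0.40 between the FBP1 and empty vector arrays and 0.46 between the FBP1 and wt arrays. The controls differ in treatment as labelled, so their difference is not a replicate spread.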

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

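All tests of explanations in this part were chosen after the result was seen, although the settings used in the scaling test had been planned. Probes without a gene name were not used in the comparisons; of 6322 such probes detected, 254 were at least 1.5-fold higher on the FBP1 array than on both controls and 115 at least 1.5-fold lower. The wt array stood apart from the others for 150 of these probes and the empty vector array for 119. The probe farthest above both controls, ILMN_3200140, differed by 3.56 from the empty vector array and by 2.63 from the wt array.

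Genes detected on the FBP1 array and on neither control were the first pattern weighed. For the count, genes with a detection p-value under 0.05 on another array were left out, beyond the limit of 0.01 used elsewhere. This rule left out TMEM98, whose detection p-value was 0.037 on the empty vector array and whose difference from it was 2.28. Under the rule, 9 genes on the FBP1 array were at least 2-fold above the nearest control. The counts were 4 on the wt array alone and 2 on the empty vector array alone. Noise of dim probes could give such an excess at these counts. For UCHL1 the gap of 4.49 to the nearest control exceeded 2 times the largest gap of a gene counted on 1 control array only (1.98). SSX1 was left out by the rule too, with a detection p-value of 0.044 on the empty vector array. SSX1 was detected on the wt array and differed by -2.59 between the empty vector and wt arrays. The 4.49 did not exceed 2 times the size of that difference. Noise is therefore argued against for UCHL1 only under the rule used. Each gap is to an array without detection, so the folds are lower bounds. They were 21.7-fold for UCHL1, 3.9-fold for the gap of 1.98 and 6.0-fold for SSX1. RNA of other epithelial cells on the FBP1 array is a candidate explanation that cannot be told apart from an effect of the FBP1 vector. Luminal markers had a median of 0.44, but 8 of the 11 were detected on both controls and 4 belong to other lists too. ESR1, PGR, GATA3 and TFF1, which complete the list of 15, were not among the detected members, so the median does not cover them. The list also differed between the controls (0.20), where it lay above the random lists as well. The brightest luminal markers differed unevenly from the empty vector array, with KRT8 at -0.51, KRT19 at 0.07, MLPH at 0.44, XBP1 at 0.59 and AGR2 at 1.34. They were detected on both controls too, so RNA of other cells could leave them little changed, and their values do not decide between the explanations. Among 3 probes of CDKN2A, a gene described as deleted in this line and chosen here after its values were seen, 2 were detected on the FBP1 array alone (levels 5.72 and 5.24) and 1 on no array, which would speak for other cells, or for a different stock of the line, if the deletion holds in these cultures. MTAP, looked at together with CDKN2A, had a detection p-value under 0.01 on the FBP1 array alone. Its levels were 5.32 there, 4.58 (wt) and 4.86 (empty vector). Its detection p-value of 0.031 on the empty vector array would leave it out under the rule of the count. All these probes were dim.

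Lower genes of the G2 and M phases were the second pattern. A scaling effect is argued against, because the list median stayed at -0.64 or lower under median scaling, cyclic loess, no background correction and the authors' processed values. Loss of short-lived transcripts in RNA handling is argued against too, with a median of 0.06 for such transcripts. Fewer dividing cells in that culture remain a candidate explanation, since replication-dependent histones also lay below the random lists, at -0.57, although arrays of this kind may read mainly the polyadenylated forms of histone transcripts. Whether such a difference came from the FBP1 vector, from cell density or time in culture, or from an admixture of other cells was not tested, because each group is 1 array.

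Higher NF-kB and inflammatory genes were the third pattern. The empty vector array was low on this list (-0.56 against the wt array), and a low level there may account for much of the difference. Against the wt array the list still lay above the random lists, at 0.35, but 8 members were at least 1.5-fold higher and 4 lower, so this explanation is left open. An effect of the FBP1 vector and a difference between cultures may both give such values, and with 1 array per group neither was tested.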

How the results depend on the processing

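These tests of settings were planned before the values were seen, except normexp fitted to all probes with an offset of 50, which was chosen after seeing the data. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out. Of 74 alternative counts 42 were classed as the same and 32 as moved, and of 980 list medians 872 as the same and 108 as moved. Of 3187 single-gene values 2824 were classed as the same, 362 as moved and 1 as reversed. The reversed value was IL13RA2 against the empty vector array, 0.72 in the main setting and -0.58 against the mean of both controls. The class of the same values was wide. With median scaling the genes lower than the empty vector array went from 751 to 987 and those below both controls from 394 to 520. Both were classed as the same, as was the heat shock median that went from -0.17 to -0.11 with cyclic loess. FBP1 was higher on the FBP1 array under every setting. The lists of hypoxia, interferon-stimulated, NF-kB, cholesterol synthesis, MYC, S phase, G2 and M phase and histone genes lay outside the random lists against both controls in all 9 alternative settings, luminal markers in 8, and heat shock genes against the empty vector array in 4. Counts shrank where background was kept or the offset raised, because both compress differences of dim genes, and of the genes then apart from both controls 350 of 350 without background correction, 472 of 472 with an offset of 50, 427 of 427 with normexp on all probes and 263 of 272 with the authors' processed values were apart in the main setting too.

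Counts at least 1.5-fold higher and lower are given in the order FBP1 against empty vector, FBP1 against wt, empty vector against wt, and FBP1 apart from both controls. Only counts classed as moved are listed. Without background correction they were 321 and 214, 516 and 349, 93 and 89, and 223 and 127. With an offset of 50 they were 443 and 316, 657 and 494, 162 and 144, and 288 and 184. With the authors' processed values they were 265 and 143, 416 and 258, 66 and 65, and 188 and 84. With normexp fitted to all probes and an offset of 50 they were 406 and 286, 605 and 434, 138 and 135, and 263 and 164.

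List medians that moved are given for the FBP1 array against the empty vector array, for the lists outside the random lists against both controls. Of the others, Notch targets ranged from -0.42 to -0.15, mesenchymal genes from -0.28 to -0.16 and Wnt targets from -0.25 to -0.14 over the alternatives, with Wnt targets outside the random lists in 8 of 9. Without background correction they were -0.16 for MYC targets, 0.46 for NF-kB, -0.69 for G2 and M phase, 0.33 for cholesterol synthesis, -0.43 for histones and 0.22 for luminal markers. With an offset of 50 they were -0.18 for MYC targets, 0.63 for NF-kB and 0.29 for luminal markers. With a detection p-value under 0.05, NF-kB was 0.54 and luminal markers 0.29; with no detection filter, NF-kB was 0.30 and luminal markers 0.07. With the mean of the detected probes of a gene, interferon-stimulated genes were 0.21. With the authors' processed values the medians were -0.15 for MYC targets, 0.23 for interferon-stimulated genes, 0.39 for NF-kB, -0.32 for S phase, -0.64 for G2 and M phase, 0.32 for cholesterol synthesis and 0.18 for luminal markers. With normexp fitted to all probes and an offset of 50 they were -0.18 for MYC targets, 0.56 for NF-kB, 0.37 for cholesterol synthesis, -0.44 for histones and 0.28 for luminal markers. Against the mean of both controls they were 0.59 for hypoxia, -0.45 for MYC targets, 0.48 for NF-kB, 0.36 for cholesterol synthesis and 0.30 for luminal markers. Medians against the wt array moved too. Over the alternatives they ranged from -0.79 to -0.43 for histones, from 0.07 to 0.36 for luminal markers and from 0.04 to 0.38 for epithelial genes.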

Other observations

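Values in this part were picked out after the data were seen, apart from the named genes and lists. Single genes of lipid and sterol handling and of the secretory stress response were higher on the FBP1 array, while other members of their lists, such as ELOVL6 (-0.47), CALR (-0.45) and SREBF2 (-0.33), were below the empty vector array. The desaturase gene SCD was 1.78-fold above the empty vector array and 1.91-fold above the wt array, LPIN1 2.05-fold and 2.68-fold, LSS 2.34-fold and 2.05-fold, HSPA5 1.86-fold and 1.74-fold, and DNAJB9 1.86-fold and 1.84-fold. GDF15, a secreted stress hormone gene, was 3.18-fold and 2.55-fold higher although the p53 target list it belongs to had a median of 0.00 against the empty vector array. The matrix glycoprotein gene THBS1 was 2.37-fold below the empty vector array and 3.34-fold below the wt array, and the tissue factor gene F3 differed by -0.72 and -1.32 (log2).

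The side on which the wt array stood varied by gene. TIMP3, an inhibitor of matrix proteases, was 2.51-fold higher on the empty vector array than on the wt array and a further 1.59-fold higher on the FBP1 array, and S100A4 was 3.09-fold and 1.33-fold higher in the same order. THY1 was 2.72-fold lower on the empty vector array than on the wt array, and was not detected on the FBP1 array, where it was at least 1.2-fold below the empty vector array. The actin-bundling gene LCP1 was 2.63-fold lower on the empty vector array and 1.33-fold lower again on the FBP1 array.

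A second detected probe of the same gene gave a partial check within these arrays. Of 156 genes above both controls with such a probe, it pointed the same way against both controls for 111 (71.2%), and of 105 genes below both controls for 95 (90.5%); it reached 1.5-fold against both for 47 and 38 of them. Over all 3503 genes with a second detected probe, 34.8% of these probes lay above both controls and 40.1% below both. None of the 14 further detected probes of the genes named as farthest from both controls pointed the other way, although some differed little. Against the empty vector array the second probe of TMEM98 stood at 0.29 and the further probes of PSG4 at -0.12 and -0.01. The further probes of CSF1 stood at 1.08 and 0.88, against 2.45 for its brightest.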
